A study of Mus musculus with 11 samples.

How the data were processed

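RNA was measured in fluorescent interneurons sorted from the telencephalon of mouse embryos at stage E14.5, in 5 wild-type samples and 6 samples with an Arx polyalanine expansion, per the labels. Total RNA was extracted with Trizol and labelled as biotinylated cRNA for a single-colour Affymetrix array, per the labels' protocols. The deposited values are log2 GCRMA summaries of 22690 probe sets per array, and the submitters' processing notes name GCRMA and limma without versions. GCRMA as commonly run adjusts background by probe sequence, normalises quantiles between arrays and summarises the probes of a set. The values bear marks of it, with a shared floor of 2.25 that held 39.3% to 41.4% of the values on each array and medians from 2.88 to 3.09. The floor hides differences of dim genes. The settings used by the authors are not given in the sources used here. Scanner files were not used here, so the background step and the normalisation were kept as deposited. No 2 arrays were alike enough to be a repeated deposit, as the closest pair differed by 0.27 (root mean square, log2).

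Genes were named from the platform annotation supplied with the values. Of the probe sets, 64 were controls and were left out, 20380 carried 1 gene symbol, 691 carried several and 1555 were unnamed there. No gene-level value was taken from a probe set with several symbols. Arx, the mutated gene, has no probe set paired with it there, so the comparison of its level planned before the data were examined was not run. No coordinates are given, since the array values carry no genome build.

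The dimmest 40% of probe sets by their mean over all 11 arrays were left out (mean under 2.32), which kept 13575. For each gene the probe set with the highest mean was kept, and 3010 genes had more than 1 to choose from, which left 7938 genes. Mutant and wild-type samples were compared with limma (lmFit and eBayes with an intensity trend, 9 residual degrees of freedom, prior 1.89), with no covariate and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Intervals are 95% intervals of the fit. Gene lists were fixed before the data were examined and held 528 genes, of which 453 had a probe set and 329 were measured after the filter, 3 of them under a synonym. Lists with at least 5 measured members were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over 23 lists. Camera with an estimated correlation and fry stand beside it. Single measures of array quality were compared with two-sided exact permutation tests over all 462 splits. Principal components were taken from the gene-level values, and the side of the first component gave 2 array sets, a choice made after seeing the data.

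The rule for naming genes was fixed before the data were examined. It took Arx, the 12 largest differences in each direction among called genes, filled up to 10 genes with the smallest p where fewer passed, and up to 4 genes with the smallest p in each list. Alternatives were other filters on dim probe sets, quantile normalisation, median centring, other ways to choose probe sets, no intensity trend, array weights, a residual component, the replicate number as a block, other thresholds, and leaving out each sample in turn. Added after seeing the data were the array set as a block, each set alone, and leaving out wild type 1 and 2 or 1 to 3.

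The steps were tested on simulated data with the spread of these 7938 genes and 5 against 6 arrays, in 20 runs with 200 changed genes each. The fit recovered 33.2% of genes changed by 0.5, 77.8% of those changed by 1 and 97.3% of those changed by 2 on the log2 scale, and 4.6% of calls were false. A list shifted by 0.5 was detected in 20 of 20 runs, with 0.15 other lists called per run. The simulated genes varied independently, which real genes do not. Each run also held 200 changed genes and no array sets, while the real comparison called 2 genes. With more changed genes the adjusted threshold is easier to pass, so these shares are not the power of the real comparison. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.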

Results

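Gene expression was measured in developing interneurons sorted from the telencephalon of mouse embryos at stage E14.5. A transgene that places green fluorescent protein under Dlx5/6 control marked the cells, and the fluorescent cells were collected with a cell sorter. The embryos were wild type, or carried an expansion of a polyalanine tract in Arx, an X-linked homeobox gene expressed in these cells whose mutations cause developmental epilepsies. Total RNA of 5 wild-type and 6 mutant samples was hybridised to 11 single-colour Affymetrix arrays. Levels are log2 GCRMA values per probe set, which ran from a floor of 2.25 to 15.27, and 7938 genes were tested. The number of arrays limits the precision. The labels do not say that the samples came from separate embryos or litters, so p-values measure only the spread between these samples, which may in part be technical. Arx itself was not analysed here, because no probe set is paired with it in the annotation used, so its level was not used to check the genotype labels.

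The sorted cells carried the transcripts that define subpallial GABAergic neurons. The homeobox gene Dlx2 stood at 10.92 ± 0.33 (SD, n = 5) in wild-type and 11.16 ± 0.35 (SD, n = 6) in mutant samples. Gad1, which encodes a GABA-synthesising enzyme, stood at 9.87 ± 0.43 and 10.11 ± 0.30, and Slc32a1, the vesicular GABA transporter, at 8.62 ± 0.17 and 8.80 ± 0.21. Markers of other lineages were not evenly spread over the samples. Neurod6, a gene of pallial glutamatergic neurons, stood at 7.50, 6.39 and 5.50 in wild type 1, 2 and 3, and between 2.25 and 2.54 in the other 8 samples. Hba-x, an embryonic globin, stood at 7.68, 7.43 and 4.49 in the same samples and at 4.21 in mutant 4. Averaged over the markers of pallial, erythroid, endothelial, pericyte and microglial cells, wild type 1, 2 and 3 stood at 4.92, 4.15 and 3.51, wild type 4 and 5 at 2.92 and 3.10, and the mutants between 2.94 and 3.41.

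The labels describe male embryos, and 10 of the 11 samples had the brightest probe set of Xist, the RNA of the inactive X chromosome, at the floor. In wild type 5 it stood at 9.49. The other Xist probe sets stood at 4.32 and 3.44 in wild type 5 and at the floor in the rest, except for a value of 2.35 in mutant 4 on the dimmer one. The Y-linked genes Eif2s3y and Kdm5d stood at 2.69 and 2.33 in that sample, against 6.08 ± 0.45 and 5.06 ± 0.28 (SD, n = 10) in the others. Wild type 5 was kept in the comparison as labelled. Without it, 3 genes were higher in mutant samples in place of 2.

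**Figure D1:**
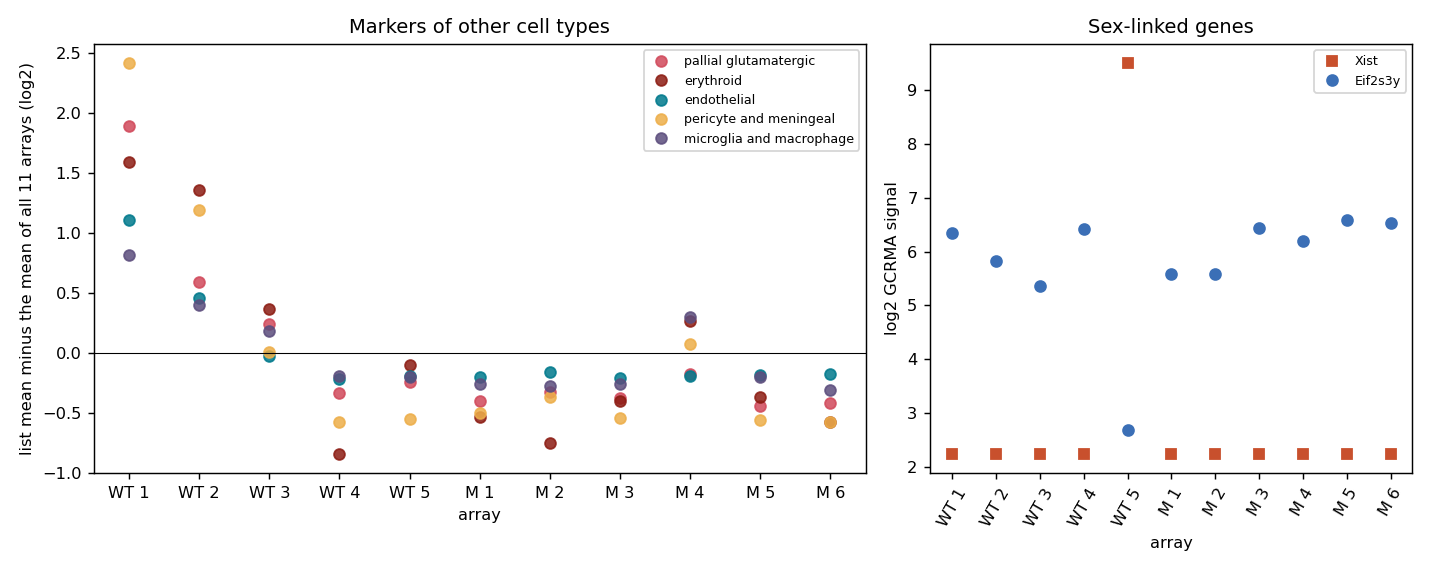
Left, mean of each list of markers of another cell type on each array, as a log2 difference from the mean of all 11 arrays; right, log2 signal of Eif2s3y and of the brightest Xist probe set on each array (WT, wild type; M, mutant). All 5 lists lie highest in wild type 1, and wild type 5 alone has this Xist probe set above the floor, at 9.49.

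The arrays fell into 2 sets on the first principal component, which held 42.8% of the variance between them. Wild type 1 to 3 with mutant 1 and 2 formed set 1, and wild type 4 and 5 with mutant 3 to 6 formed set 2. The sets were defined from the data, are not named in the labels, and both hold samples of each genotype. Array correlations (Pearson's r across genes) ran from 0.967 to 0.992 within set 1, from 0.988 to 0.995 within set 2 and from 0.959 to 0.988 between sets. Median signal, the share of probe sets at the floor, and the 3′ minus 5′ signal of the actin and Gapdh control probe sets showed no difference between genotypes past the threshold (two-sided exact permutation tests over 462 splits, p from 0.0758 to 0.375, adjusted p from 0.416 to 0.449 over 6 measures including both principal components). Between the sets, the mean of the array medians was 2.97 in set 1 and 2.90 in set 2 (exact permutation p = 0.00217, unadjusted). The mean share at the floor was 40.2% and 41.0% (exact permutation p = 0.0173, unadjusted). The sets were defined from these same arrays, so these p-values are not independent of them. Values within each set, or with the set as a block, are given beside the leading results.

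**Figure D2:**
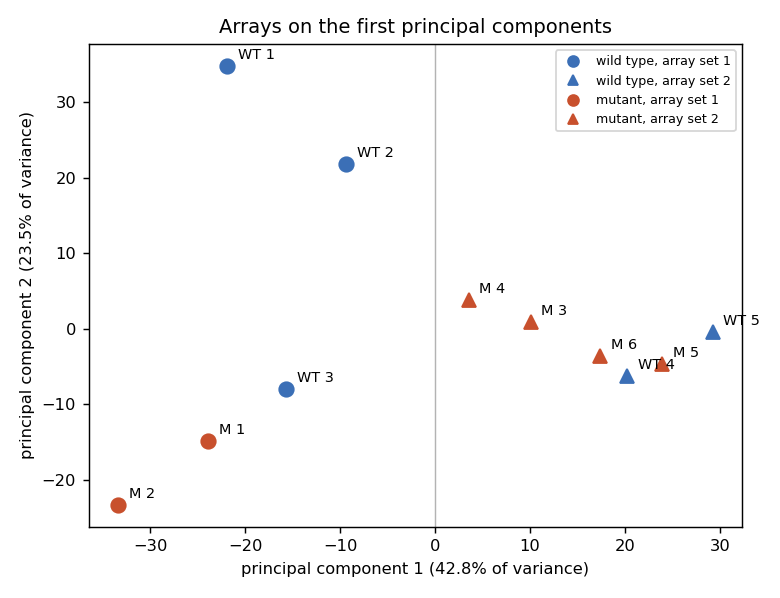
Position of each array on principal component 1 (42.8% of variance) and principal component 2 (23.5%) of the gene-level log2 values; colour gives the genotype and marker shape the array set. Both genotypes lie on each side of the line at 0 that parts the sets, and wild type 1 and 2 lie highest on the second component.

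The series asks which genes the Arx expansion changes in these cells. In mutant samples, 2 genes were higher and 0 were lower at an adjusted p under 0.05 by limma. Lmo1, which encodes a LIM-only transcriptional cofactor, rose from 8.80 ± 0.50 (SD, n = 5) to 11.43 ± 0.23 (SD, n = 6), a 6.22-fold difference (95% interval 4.49 to 8.60; limma adjusted p = 0.000569). Cadps2, which encodes an activator of dense-core vesicle release, rose from 3.95 ± 0.33 to 6.60 ± 0.42, a 6.28-fold difference (95% interval 4.47 to 8.84; limma adjusted p = 0.000569). For both genes every mutant sample lay above every wild-type sample. The log2 difference of Lmo1 was 2.95 in set 1 and 2.43 in set 2, and that of Cadps2 was 2.36 and 2.80. Each was read by a single probe set. With wild type 1 to 3 left out, which carried the other-lineage markers, the log2 differences were 2.56 and 2.65, and neither call held with 2 wild-type samples left (limma adjusted p = 0.0741 and 0.0760).

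Beyond these calls, the 8 further genes with the smallest p did not pass the threshold. Lmo4, another LIM-only gene, stood at 9.99 ± 0.36 (SD, n = 5) in wild-type samples and 1.01 above that in mutants, a 2.02-fold difference (limma adjusted p = 0.0712). It passed in 3 of 10 planned settings, with the dimmest 60% of probe sets left out (limma adjusted p = 0.0199), quantile normalisation (0.0204) and the residual component (0.0206). It passed as well in 1 of the 11 settings without 1 sample, that of wild type 5 (0.00142), and with the array set as a block (0.0293). Cxcr4, a chemokine receptor that guides migrating interneurons, had the smallest p of any gene with a lower mean in mutants, at 8.17 ± 0.27 against 7.13 ± 0.36 (log2 difference -1.04, limma adjusted p = 0.332). Its difference was -0.95 in set 1 and -0.93 in set 2, and every mutant sample lay below every wild-type sample. Csrp2, a LIM domain protein gene, differed by 0.61 (limma adjusted p = 0.275). Nptx2, a neuronal pentraxin gene, differed by 0.66 and passed only with the array set as a block (limma adjusted p = 0.0293). Stac2 differed by 1.10, Syn2, which encodes a synaptic vesicle protein, by 0.88, Klhl7 by 0.45 and Mid1ip1 by -0.48, with limma adjusted p from 0.931 to 0.948. The second probe set of Syn2 differed by 0.15, that of Klhl7 by 0.27, and that of Nptx2 lay at the floor in all samples.

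**Figure D3:**
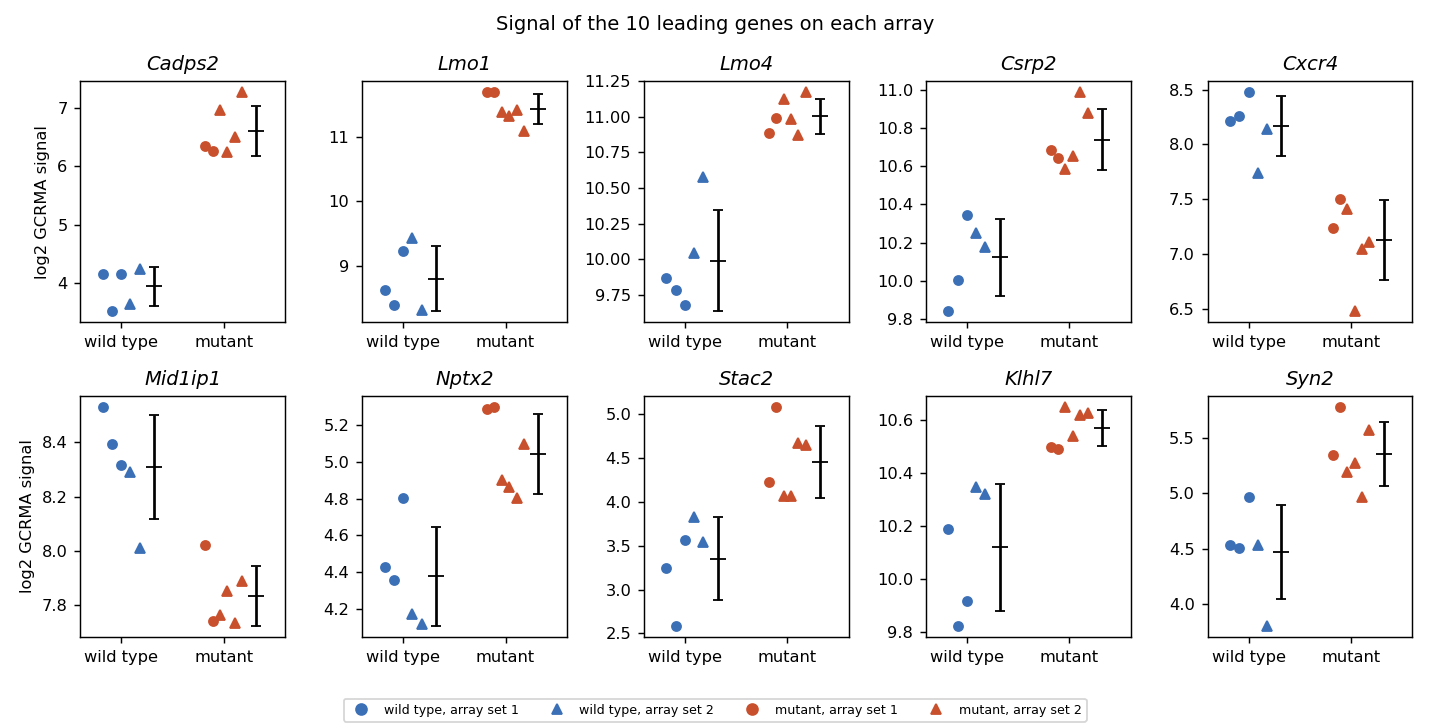
Log2 GCRMA signal of the 10 genes with the smallest p on each array, by genotype, with marker shape for the array set; bars give the mean and SD of the group. Lmo1 and Cadps2 separate the genotypes by 2.64 and 2.65 on the log2 scale, and the other 8 genes did not pass the threshold over all genes.

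Over all 7938 genes, 155 were higher and 83 lower at an unadjusted limma p under 0.05, which is 3.0% of those tested. That share is smaller than the one chance gives at this p, in a fit that leaves the difference between array sets in the residual spread. The groups did not overlap for 22 genes higher and 5 genes lower in mutants, where chance gives 0.216% of genes in each direction. With both directions together, chance gives more such genes than were seen, so a lack of overlap alone does not set a gene apart from chance. With the array set as a block, 5 genes were higher and 0 lower by limma, with 887 genes at an unadjusted p under 0.05. Those 887 are a larger share of the 7938 genes than chance gives at this p. The sets were defined from these values and genes do not vary independently, so that share is not a count of changed genes. The 5 genes called were Lmo1, Cadps2, Lmo4, Nptx2 and Dlx1as, the last chosen after its values were seen. Dlx1as is the antisense transcript at Dlx1, and its log2 difference with the block was 0.97.

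Of the 10 measured genes in a list of ARX targets, Lmo1 rose and the other 9 did not pass the test over all genes. Adjusted over the list alone, 1 was higher (Lmo1) and 2 were lower, Cxcr4 and Lhx8. Lhx8, a LIM homeobox gene of cholinergic and medial ganglionic eminence neurons, stood at 9.39 ± 0.61 in wild-type and 8.49 ± 0.46 in mutant samples, with differences of -0.30 in set 1 and -1.34 in set 2. Mef2c differed by -0.33. The members had a mean difference of 0.06 and a median of -0.03, and camera ranked the list downward, so the signs differ (camera adjusted p = 0.417). By fry's mixed test, which looks for change in either direction, this list alone passed (adjusted p = 1.62e-07, with 0.137 for the next list). The list holds Lmo1, already called over all genes, and a mixed test can pass on 1 such member. No test without Lmo1 was run, so the pass is no evidence on the other 9 members. With all probe sets tested its mean was -0.03 and camera passed it (adjusted p = 0.0490).

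The lists of interneuron identity did not pass with the settings used throughout, and 3 of them each passed in 1 of 13 other settings that keep all 11 samples. Of 9 GABA synthesis and signalling genes, 8 had a higher mean in mutants, 0 passed, and the mean difference was 0.23 (camera adjusted p = 0.129). Gad2 differed by 0.48 (1.06 in set 1 and -0.05 in set 2) and Slc12a5, the potassium-chloride cotransporter gene, by 0.50 (0.84 and 0.40). The list passed with array weights (mean 0.30, camera adjusted p = 0.0388), without wild type 1 (0.34, 0.0286) and without mutant 5 (0.26, 0.0454). Of 10 subpallial determinants, 8 had a higher mean and 0 passed (mean 0.13, camera adjusted p = 0.179), with Dlx5 at a difference of 0.30 and Dlx2 at 0.24. That list passed with array weights (mean 0.18, camera adjusted p = 0.0388) and without wild type 1 (0.22, 0.0478). With 1 sample left out the subpallial mean ran from 0.0803 to 0.223. In the medial ganglionic eminence list 0 of 10 passed (mean -0.15, camera adjusted p = 0.131), and the list passed as lower with plain probe sets, those with the suffix _at alone (mean -0.31, camera adjusted p = 0.0172). Its mean ran from -0.31 to -0.035 over planned settings and from -0.245 to -0.0778 with 1 sample left out. In that list Npy, a neuropeptide of somatostatin-class interneurons, differed by -0.74. Satb1 and Sox6, transcription factors of that lineage, differed by 0.63 and 0.82. The caudal ganglionic eminence list had a mean of 0.04 (0 of 11 passed, camera adjusted p = 0.417), with -0.17 in set 1 and 0.63 in set 2, and passed without wild type 2 (mean 0.20, camera adjusted p = 0.0469). Htr3a differed by 0.50 (0.06 in set 1 and 1.12 in set 2) and Reln by -0.63 (-0.58 and -0.28). Wild type 5 stood lowest for Htr3a at 3.98, with the other wild-type samples from 5.38 to 6.28. Wild type 1 stood highest for Reln at 7.66, with the other wild-type samples from 5.47 to 7.08. The lateral ganglionic eminence and striatal list had a mean of 0.01 (0 of 17 passed, camera adjusted p = 0.776), with Pbx3 at 0.43 and Meis2 at -0.43; its camera direction was down, against the sign of its mean.

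Members of the cholinergic list were lower as a group by camera. All 5 measured members had lower means in mutants, with a mean difference of -0.48 (camera adjusted p = 0.00835), while 0 passed singly. The call was lost with an estimated correlation (adjusted p = 0.263), with the array set as a block (0.0659), without wild type 4 (mean -0.23, adjusted p = 0.110) and without mutant 3 (-0.29, 0.0643). It held in 10 of 12 planned settings and in 9 of the 11 without 1 sample. Lhx8 led the list, Zic1 differed by -0.84, Zic4 by -0.39, Gbx2 by -0.24 and Isl1 by -0.0061. Chat and Ntrk1 had no probe set with their symbol alone, and Slc18a3, Slc5a7 and Ngfr were not among the measured members. The list call therefore does not cover these genes. The mean was 0.17 in set 1 and -1.0 in set 2.

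Genes of migration, growth and neuronal maturation showed no group shift past the threshold over all samples. Of 28 migration and guidance genes 0 passed over all genes and 1, Cxcr4, was lower adjusted over the list alone (mean -0.04, camera adjusted p = 0.203). Vldlr, a reelin receptor gene, differed by 0.70 (0.98 in set 1 and 0.55 in set 2) and Dab1, its adaptor, by -0.73 (-1.05 and -0.07). Dab1 stood at 5.05 and 4.72 in wild type 1 and 2 and between 2.80 and 3.49 in the other samples. The cell cycle list had a mean of -0.03 (0 of 37 passed, camera adjusted p = 0.211), with Aurka at 0.42 and Mcm4 at -0.27, and passed without wild type 4 (mean -0.09, camera adjusted p = 0.0196) and without mutant 5 (-0.09, 0.00626). The pan-neuronal list had a mean of -0.05 (0 of 24 passed, camera adjusted p = 0.420), with the neurofilament gene Nefm at -0.67. The epileptic encephalopathy list had a mean of -0.01 and a median of 0.0005 (0 of 15 passed, camera adjusted p = 0.933), and the sodium channel gene Scn1a differed by 0.42.

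Progenitor and Notch signalling genes were lower as a group by camera (mean -0.35, 19 of 26 lower, camera adjusted p = 0.000494), with 0 passing singly. The call was lost with an estimated correlation (adjusted p = 0.387), with the array set as a block (0.311) and without wild type 1 (mean -0.10, adjusted p = 0.346). Other losses were with array weights (mean -0.07, camera adjusted p = 0.482), with the dimmest 60% left out (-0.15, 0.0611) and by fry's directional test (adjusted p = 0.569). It held in 9 of 13 planned settings and in 10 of the 11 without 1 sample. The mean was -0.63 in set 1 and 0.18 in set 2, so it did not hold within both sets. Without wild type 1 to 3, with 2 wild-type samples left, the list passed as higher in mutants (mean 0.24, adjusted p = 0.0370). Fabp7, a radial glial lipid-binding protein gene, stood at 12.32, 11.97 and 10.02 in wild type 1, 2 and 3 and between 8.14 and 10.70 in the other samples. Aldoc differed by -1.77 (-3.42 in set 1 and 0.33 in set 2) and Id3 by -0.68 (-0.81 and -0.52). The Wnt and beta-catenin list was also lower by camera (mean -0.11, 14 of 20 lower, camera adjusted p = 0.0251), with 0 passing singly. That call was lost with an estimated correlation (adjusted p = 0.387), with the array set as a block (0.487) and without wild type 1 (mean -0.0057), wild type 2 (-0.0549), mutant 3 (-0.0924) or mutant 5 (-0.0743). Among other planned settings it was lost with array weights (mean -0.0062) and with the dimmest 60% left out (0.0873). It held in 5 of 13 planned settings and in 7 of the 11 without 1 sample. Without wild type 4 or wild type 5 the mean was -0.18. Its mean was -0.16 in set 1 and 0.11 in set 2. Ccnd1, the cyclin D1 gene, differed by -1.45, with -2.30 in set 1 and 0.13 in set 2. Set 1 holds wild type 1, 2 and 3, the samples in which markers of other lineages stood highest.

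Among the stress and survival lists, 1 passed by camera over all samples. The immediate early list was lower by camera (mean -0.18, 9 of 11 lower, 0 passing singly, camera adjusted p = 0.0333). Its call was lost with an estimated correlation (adjusted p = 0.245), with the array set as a block (0.0797) and without wild type 1 (mean -0.158), wild type 3 (-0.195), wild type 5 (-0.114), mutant 1 (-0.154), mutant 3 (-0.175), mutant 4 (-0.188) or mutant 5 (-0.164). It held in 8 of 13 planned settings and in 4 of the 11 without 1 sample. Jun differed by -0.89. The apoptosis and p53 list had a mean of 0.21 (13 of 17 higher, 0 passed, camera adjusted p = 0.0786). Ccng1 and Trp53inp1, both p53 targets, differed by 0.73 and 0.48, and Sesn2 by 0.63. That list passed in 4 of 13 planned settings and without mutant 2 (mean 0.218, adjusted p = 0.0476) or mutant 6 (0.230, 0.0483), and it was the 1 list called with the dimmest 60% of probe sets left out (0.363, adjusted p = 0.0147). The unfolded protein response list had a mean of -0.08 (0 of 23 passed, camera adjusted p = 0.0532), with the chaperone gene Hspa5 at -0.21 and Dnajb9 at 0.27. Hspa5 differed by -0.41 in set 1 and 0.05 in set 2, and Dnajb9 by 0.43 and 0.18. The list passed in 3 of 13 planned settings and without mutant 5 (mean -0.0913) or mutant 6 (-0.0991). The heat shock list had a mean of -0.12 (0 of 13 passed, camera adjusted p = 0.0627). It passed in 1 of 13 planned settings and without wild type 3 (mean -0.191), mutant 3 (-0.155), mutant 4 (-0.151), mutant 5 (-0.170) or mutant 6 (-0.160). Over all settings without 1 sample its mean ran from -0.191 to -0.001. It passed as well with the array set as a block (camera adjusted p = 0.0127), with means of -0.48 in set 1 and 0.03 in set 2.

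Markers of other cell types were lower in mutants as 5 lists by camera, and the difference lay in set 1. All 5 calls were lost with an estimated correlation. The pallial glutamatergic list had a mean of -0.79, with 11 of 11 members lower (camera adjusted p = 2.09e-08, and adjusted p = 0.226 with an estimated correlation), and Neurod6 differed by -2.45 and Tbr1 by -1.13. The erythroid list had a mean of -0.87 (9 of 9 lower, camera adjusted p = 4.96e-05, and adjusted p = 0.226 with an estimated correlation), with Hba-x at -2.22. Adjusted over the list alone, 1 erythroid gene, Car2, was lower (log2 difference -0.85). The pericyte and meningeal list had a mean of -0.91 (8 of 8 lower, camera adjusted p = 2.13e-05, and adjusted p = 0.263 with an estimated correlation), with the collagen gene Col4a1 at -1.69. The endothelial list had a mean of -0.41 (8 of 9 lower, camera adjusted p = 0.000180, and adjusted p = 0.226 with an estimated correlation), with the tight junction gene Cldn5 at -1.51. The microglia and macrophage list had a mean of -0.37 (10 of 12 lower, camera adjusted p = 6.25e-05, and adjusted p = 0.226 with an estimated correlation), with Laptm5 at -1.06. No member passed over all genes in these lists (0 in each by limma). In set 1 the means were -1.27, -1.75, -1.64, -0.70 and -0.73 for the pallial, erythroid, pericyte, endothelial and microglial lists. In set 2 they were -0.06, 0.20, 0.16, 0.02 and 0.08. All 5 calls held in each of the 11 settings without 1 sample. Without wild type 1 the means were -0.42, -0.59, -0.43, -0.19 and -0.21, in the same order. With array weights the microglial call was lost (mean -0.12, adjusted p = 0.0806). With the array set as a block the adjusted p ran from 0.000247 for the pallial to 0.0225 for the endothelial list. That block fits 1 genotype difference for both sets, and leaving out 1 sample never removes wild type 1 to 3 together. All 5 calls were lost in set 2 alone (camera adjusted p from 0.215 to 0.798). They were lost as well with wild type 1 to 3 left out (camera adjusted p from 0.284 to 0.943). In both settings 2 wild-type samples were left.

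The diencephalic and hypothalamic list had a mean of -0.10 (0 of 5 passed, camera adjusted p = 0.211). That mean ran from -0.30 to -0.0406 over planned settings and from -0.139 to -0.0047 with 1 sample left out. The oligodendrocyte precursor, choroid plexus and sex chromosome lists had 4, 2 and 4 measured members, fewer than the 5 needed for a test. Their mean differences were -0.15, 0.64 and 0.11, and 0 of these genes passed over all genes by limma. In all, 9 of 23 lists passed by camera, 0 with an estimated correlation, 0 by fry's directional test, 1 by its mixed test (ARX targets) and 6 with the array set as a block.

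**Figure D4:**
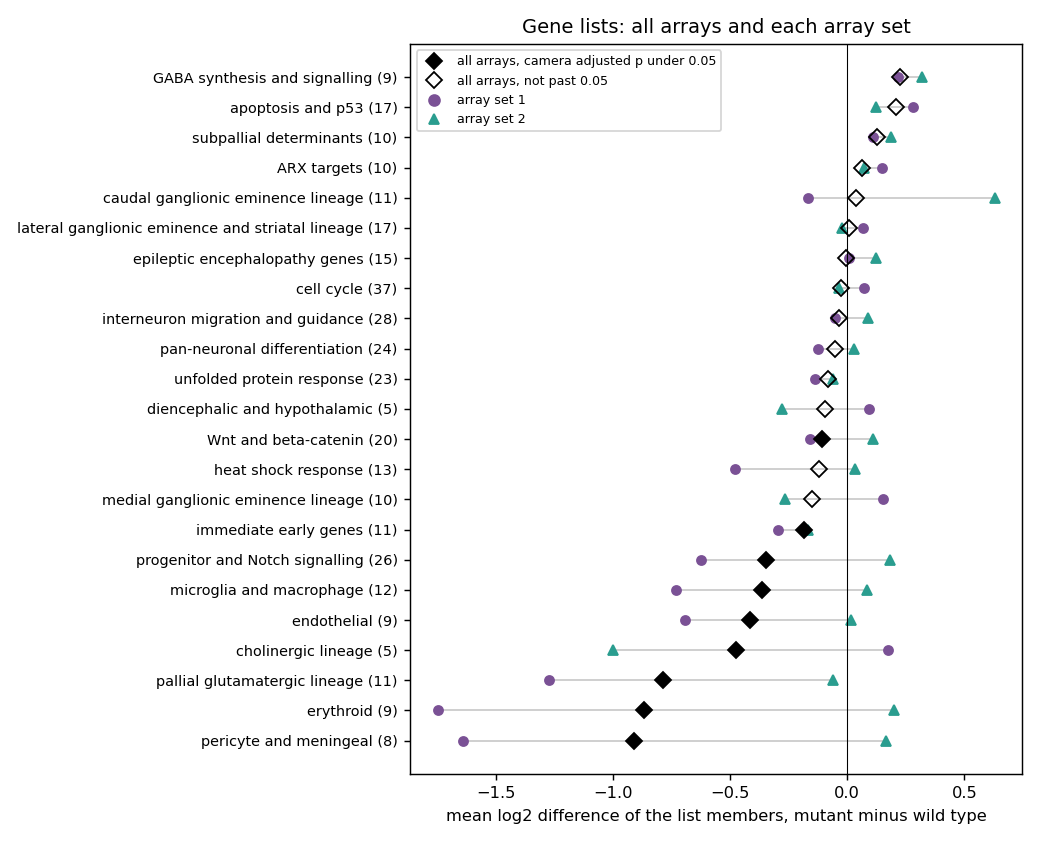
Mean log2 difference (mutant minus wild type) of the measured members of each of the 23 lists, with the number of members in brackets; diamonds use all arrays, circles array set 1 and triangles array set 2. The erythroid list lies at -1.75 in set 1 and 0.20 in set 2, and the ARX target list near 0 in both.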

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

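The tests of array sets, other-lineage cells, a shared genotype difference in the lists, single probe sets, sex-linked genes and the genotype of wild type 5 were chosen after the results were seen, and the count over splits of the samples was planned. Among 72 groups of samples checked for a sample apart from its group, 9 had one, and independent groups would give about 3.6 by chance. The groups are not independent. Xist, Eif2s3y and Kdm5d all flagged wild type 5, and the sex-linked genes were tested after the results were seen. The GABA and subpallial lists share Gad1 and Gad2 and flagged the same sample, and the pericyte and microglial lists both flagged mutant 4. The excess over chance is therefore not evidence by itself.

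Wild type 5 stood apart from its group in Xist (9.49), Eif2s3y (2.69) and Kdm5d (2.33), against labels that describe male embryos. RNA from a female embryo is a candidate explanation: Eif2s3y lay below the mean of the other 10 samples by 7.49 of their SDs (difference -3.39). An equal mixture of male and female RNA is argued against, since it would lower the Y-linked genes by about 1 on the log2 scale and Kdm5d was lower by more (difference -2.73). A mutant sample labelled wild type is argued against by Lmo1 (8.32) and Cadps2 (4.24) in wild type 5. Both lay below the lowest mutant (11.09 and 6.25), the smaller distance being 2.01. They were picked from a fit that counted wild type 5 as wild type, so a lack of overlap came with that choice. The fit without wild type 5 called both as well (log2 difference 2.52 and 2.73, limma adjusted p = 0.00142 and 0.00155). Lmo4, also called there, stood at 10.58 in wild type 5 and 10.87 in the lowest mutant. A female embryo taken as male, another wild-type sample in its place, and a mixture with a small share of male RNA stay open, and no biological explanation was tested.

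Markers of pallial, erythroid, endothelial, pericyte and microglial cells were lower in mutants, with a mean over the 5 lists of -0.67. A difference between the array sets as the whole account is argued against, since the difference within set 1 was -1.22. A difference shared by the mutant samples cannot be told apart from one of wild type 1 to 3 alone: wild type 4 and 5 lay at -0.0427 from the mutant mean (mutant SD 0.18), but they are the 2 wild-type samples left once the highest were picked. Cells or RNA of other lineages in wild type 1 to 3 cannot be told apart from another feature of those samples either: 89.8% of the 49 members (44), and 66.7% in the erythroid list, were higher there than in wild type 4 and 5, but these samples were picked for standing highest on the lists and lie in the other array set. Neurod6, Hba-x and Cldn5 reached 7.50, 7.68 and 6.11 in wild type 1, the sort should remove such cells, 1 of the members stands in another list too, and 9 had a mutant mean over 4.

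Lmo1 and Cadps2 were the genes called higher in mutants. The array sets are argued against, since the smaller difference within a set was 2.36. A lack of overlap in part of the samples adds nothing, since both genes were picked from all samples and showed none there. Other-lineage cells in wild type 1 to 3 are argued against too, since against wild type 4 and 5 alone the smaller difference was 2.56. For Lmo1 that difference was 2.56 (wild-type SD 0.79, n = 2) against 2.64 over all samples (SD 0.50, n = 5), and the adjusted p rose to 0.0741 with 2 wild-type samples left, and for Cadps2 it was 2.65 (wild-type SD 0.41, n = 2) against 2.65 (SD 0.33, n = 5), with an adjusted p of 0.0760. An artefact of a single probe set cannot be told apart from a change of the gene, as 0 further probe sets of either gene lay above the floor. The real split gave 2 genes higher, 1 of 100 splits drawn (the real one) gave as many, and the highest of the others drawn was 0. The drawn splits ignore the array sets, and the split along the sets, which was not drawn, gave 827 and 793. With the set as a block 5 genes were higher in mutants. No splits within the sets were drawn, so chance is argued against only for splits that ignore the sets, and is not excluded. A genotype effect stays open as a hypothesis.

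In wild type 1 the mean of the GABA list was 7.32, against 6.70 to 6.79 in the other wild-type samples. In the same sample the mean of the subpallial list was 7.66, against 7.15 to 7.23. In mutant 6 the immediate early list stood at 6.06, against 5.48 to 5.66 in the other mutants. In mutant 4 the pericyte list stood at 3.05, against 2.39 to 2.61, and the microglial list at 3.14, against 2.53 to 2.63. In mutant 3 the diencephalic list stood at 2.57, against 3.02 to 3.24.

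Probe sets with several symbols were outside the gene-level comparison. With all probe sets tested, 1422607_at differed by 1.03 (6.92 ± 0.27 in wild-type and 7.95 ± 0.16 in mutant samples, limma adjusted p = 0.0361). In the same fit, 1450684_at differed by 1.14 (5.95 ± 0.20 and 7.09 ± 0.23, limma adjusted p = 0.0289). Both carry the same pair of symbols, Gm5454 and Etv1, and which of these genes they read cannot be told here. Etv1 belongs to the medial ganglionic eminence list, but was not measured there, having no probe set with its symbol alone.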

How the results depend on the processing

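The array set block, the sets alone and the settings without several wild-type samples were chosen after seeing the data. Lmo1 and Cadps2 kept their direction in every alternative (log2 2.43 to 2.95 and 2.36 to 2.84). Lmo1 passed in 10 of 11 planned settings and Cadps2 in 11 of 11, and both passed in all 11 that left out 1 sample (Lmo1 2.52 to 2.80, Cadps2 2.52 to 2.73). Leaving out 1 sample gave 2 to 3 genes higher, 0 lower and 7 to 12 lists. Of 2256 alternative values of genes and lists, 2099 kept their direction and side of the threshold, and of 87 alternative counts, 73 lay within 1.5 times the count reported. Most of the 2256 values belong to genes and lists that were not called. Their number therefore does not measure how far the called results hold. Except where named, the cause of a change was not tested. Signal over background limits genes near the floor, and the comparison of Arx was not run.

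With all probe sets 4 probe sets were higher, those of Lmo1 and Cadps2 and 2 that carry the same pair of symbols, Gm5454 and Etv1. Genes higher numbered 4 with the residual component, 5 with the array set block and 0 with array set 1 alone, array set 2 alone or wild type 1 to 3 left out. Cadps2 was then 2.36, 2.80 and 2.65 (adjusted p = 0.454, 0.271 and 0.0760) and Lmo1 2.95, 2.43 and 2.56 (adjusted p = 0.347, 0.283 and 0.0741), with fewer samples in each. Genes lower numbered 2 with wild type 1 to 3 left out, Cap2 (-0.54) and Kif3b (-0.44), chosen after their values were seen. Lists numbered 1 with the dimmest 60% left out, apoptosis and p53 (0.363), which was not among the 9 called; 6 of those 9 had fewer than 5 members left and were not tested (cholinergic, pallial, erythroid, endothelial, pericyte and microglial). Lists numbered 0 with an estimated correlation, 0 by fry's directional test, 1 in array set 2, 5 with wild type 1 and 2 left out and 3 with wild type 1 to 3 left out.

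The replicate numbers did not pair the samples, since same-numbered samples had correlations of 0.24, 0.13, -0.51, -0.13 and 0.67, and not every sample correlated best with its own number. With the replicate block 1 gene was higher, Cadps2, and 11 lists passed; Lmo1 was 2.71 (adjusted p = 0.129), against 4.28e-05 to 0.129 over planned settings.

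Changes of sign were mainly in lists with means near 0. The striatal list was -0.0036 with the dimmest 60% left out, -0.0063 with quantile normalisation, -0.0195 with plain probe sets, -0.0683 with all probe sets and -0.0267 with the replicate block. The migration list was 0.008 with the dimmest 60% left out, 0.0016 with median centring, 0.0591 with array weights and 0.0218 with the array set block. The cell cycle list was 0.0095 with median centring, 0.0897 with the replicate block and 0.0139 with the array set block. The epileptic list was 0.0301 with median centring, 0.0404 with array weights and 0.068 with the array set block. Array weights gave 0.0217 for the pan-neuronal and 0.0135 for the heat shock list. All probe sets gave -0.0295 for ARX targets, past the threshold (adjusted p = 0.0490, over planned settings 0.0490 to 0.924), and -0.0218 for the caudal list, and the dimmest 60% left out gave 0.0873 for Wnt. Fkbp4 was 0.119 with plain probe sets.

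The cholinergic list was 0.175 in array set 1. In array set 2 the progenitor list was 0.183, Wnt 0.109, erythroid 0.199, endothelial 0.0153, pericyte 0.164 and microglial 0.0834. Without wild type 1 and 2 the progenitor list was 0.0712 and Wnt 0.101. Without wild type 1 to 3 the progenitor list was 0.240, past the threshold upward (adjusted p = 0.0370), Wnt 0.181, erythroid 0.0746, endothelial 0.0192, pericyte 0.154 and microglial 0.0331.

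With 1 sample left out, called lists ranged from -0.978 to -0.420 (pallial), -1.20 to -0.590 (erythroid), -0.526 to -0.193 (endothelial), -1.18 to -0.430 (pericyte), -0.466 to -0.211 (microglial), with 11 of 11 past the threshold, and from -0.592 to -0.229 (cholinergic, 9), -0.500 to -0.105 (progenitor, 10), -0.183 to -0.0057 (Wnt, 7) and -0.268 to -0.114 (immediate early, 4). Lists whose sign changed ranged from -0.0856 to 0.0549 (migration), -0.116 to 0.0235 (pan-neuronal), -0.071 to 0.0785 (epileptic), -0.0537 to 0.0716 (striatal), -0.229 to 0.199 (caudal) and -0.0917 to 0.0897 (cell cycle). Single genes ranged from -0.294 to 0 (Ccn1), -0.222 to 0.0071 (Pomc) and -0.480 to 0.209 (Gbx2).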

Other observations

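The LIM-only and vesicle release hypotheses arose from the called genes, and their tests were set before their results were seen; the test of the array sets as a split of the samples was chosen after.

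Genes of regulated secretion stood among the leading genes, with Cadps2 called and Syn2 and Nptx2 higher in mean. A shared rise of vesicle release genes was tested on 21 other measured genes of that function. Their mean was 6.88 ± 0.10 in wild-type and 6.86 ± 0.14 in mutant samples, a difference of -0.0251, with 13 of 21 higher (exact permutation p = 0.747). The median difference over the members was 0.0919 with an SD of 0.256, so the mean and median differ in sign, the members go both ways, and the test shows no shared rise but does not exclude one.

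Lmo1 and Lmo4 had higher means in mutants, so a rise of the LIM-only family was tested on Lmo2, the other member measured. Lmo2 stood at 5.49 ± 0.30 in wild-type and 5.24 ± 0.72 in mutant samples, a difference of -0.25 (exact permutation p = 0.485). The difference is smaller than the spread between mutant samples, so a rise of the whole family is neither shown nor excluded. Lmo3 was not measured after the filter on dim probe sets.

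No gene was called lower in mutants by limma, with 83 at an unadjusted p under 0.05, and all 100 of 100 splits gave as many (0), so the count says nothing against chance. The 9 lists past camera's threshold are not beyond chance either among the splits drawn, since 22 of 100 gave as many and the highest other gave 11. Those splits ignore the array sets, and none were drawn within the sets. With the set as a block 6 lists passed. The split that follows the array sets called 827 and 793 genes on its 2 sides, but the sets were defined from these values, so the count is not independent evidence of a structure of the samples, and with the set as a block 5 genes were higher in mutants. The largest moderated statistic was 12.4 in the real split and 7.33 in the highest of the other splits drawn.

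Between the array sets, with genotype in the model, 2078 genes passed limma's threshold, 1009 higher and 1069 lower in set 2. The sets were defined from these values, so the count is not independent of them. Among the genes with the smallest p, Dync1h1, the dynein heavy chain gene, stood at 9.53 in set 1 and 8.21 in set 2, and Son at 10.46 and 9.14. Nme1 stood at 11.15 and 11.75. These genes were chosen after their values were seen.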
